A study of Mus musculus with 16 samples.

How the data were processed

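Liver RNA from male FvB/n mice was measured on 16 single-sample Affymetrix expression arrays in 2 experiments of 8 arrays. Per the labels' protocols, total RNA was isolated with an organic extraction reagent followed by column purification, and was copied into biotin-labelled cRNA. Groups were read from the label of each array and were never inferred from the values. The diet experiment held 2 arrays for each of 4 groups, wildtype and Alb::GC mice on a low fat diet (LFD) or a high fat diet (HFD). The other experiment held 4 arrays from untreated and 4 from AP20187-treated TTR::Fv2E-PERK mice. One field of the label of LFD wildtype replicate 2 names both genotypes, and its description, which names wildtype, was followed. One field of the label of AP20187 replicate 4 holds a single letter, and its description was followed in the same way. The labels number the arrays in sequence and do not say that each array came from its own animal, so the p-values measure the spread between these samples, which may be technical. Replicates of a group were compared before averaging. Their log2 values correlated at 0.442 to 0.658, and 1.44% to 2.46% of values were equal at 2 decimals, so none was a duplicate.

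The deposited values were a ratio per probe set and array, on a linear scale around 1, given to 2 decimals. This unit was read from the values, because what each ratio was taken against, and the scanner software and summary method, are not given in the sources used here. The smallest value was 0.01. Array medians lay between 0.94 and 1.02, and the 2 experiments were scaled apart. Within the diet experiment 23.5% of probe sets had a median within 0.02 of 1, against 14.8% in the TTR::Fv2E-PERK experiment, and the log2 medians of the 2 experiments correlated at 0.00988 across probe sets. A ratio of this kind holds no absolute level, no signal above background and no detection call. The number of arrays limits the precision, and no probe set could be ranked as bright or dim. Differences were therefore taken only within an experiment.

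Before log2, 0.05 was added to each value, and fold changes are on that scale, which understates changes that reach down to the smallest values. Arrays were kept as deposited, since their medians lay close together. The 64 control probe sets were left out, which left 22626 tested. Gene symbols came from the supplied platform annotation, which can be old. In it 20380 probe sets had 1 symbol, 1555 had none and 691 had several, which named no gene. Each of 12393 genes was represented by the probe set with the highest mean log2 value over the 16 arrays. On ratios this can favour probe sets that rise. With the probe set of smallest spread, HFD in wildtype had 747 genes up and 988 down, from 986 and 856. With AP20187 they were 1846 and 2773, from 1651 and 2653. Disagreeing probe sets are named beside the gene.

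Linear models were fitted with limma 3.58.1 in R 4.3.3, with moderated variances that follow the mean, and Benjamini-Hochberg adjustment over the 22626 probe sets at a two-sided threshold of 0.05. Files were read with the data.table package, version 1.17.8, and plots were drawn with matplotlib 3.10.9 in Python 3.11.15. The TTR::Fv2E-PERK fit used its 8 arrays and had 6 residual degrees of freedom, to which the variance model added 2.06. The diet fit used its 8 arrays with 1 spread shared by the 4 groups and had 4 residual degrees of freedom, to which the model added 2.3. Gene lists were tested with limma's camera at a preset correlation of 0.01, Benjamini-Hochberg adjusted over the lists of a comparison. Camera with an estimated correlation and limma's fry were run beside it. Fry tests whether the members of a list move, on balance, one way, without setting them against other genes. Of 35 lists, the erythroid list had too few measured members for a set test. Counts of list members past the threshold are given over all probe sets and adjusted over the list alone. Genes changed by AP20187, up to 200 per direction by size, were tested as sets in the diet experiment.

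The groups, comparisons, gene lists, the rule for named genes and most alternatives were chosen before the data were examined. The rule took, for each comparison, the 10 largest rises and the 10 largest falls among genes past the threshold whose arrays did not overlap between the groups, and up to 4 members of each list past the threshold. Where a list had none, the 2 members with the smallest p-values were given as values. Where fewer than 5 genes passed, the 5 smallest p-values in each direction were given. Ppp1r15a, Eif2ak3 and Atf4 were always named. The plan had assumed array intensities, with an offset of 16 and a filter at the 40th percentile of the mean level. Both suit intensities and not ratios around 1, so the offset was set to 0.05 and no level filter was used after the unit was known. The planned pair of settings was kept as an alternative.

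The steps were tested on simulated data built from the spread of these arrays, with 200 of 22626 probe sets changed. In the simulated AP20187 comparison, 34% of changes of 2-fold and 60% of changes of 4-fold were recovered, all 94 recovered in the right direction, and 6 unchanged probe sets were called. For HFD against LFD in wildtype the shares were 4% and 33%, with 3 unchanged probe sets called, and for Alb::GC against wildtype on HFD they were 9% and 40%, with 5 called. In the simulated AP20187 comparison, limma's camera called a raised set of genes and did not call an unchanged one. The simulated values were drawn independently for each probe set, so this did not test camera on correlated genes.

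Alternatives tried were other offsets, quantile normalization, centring of each array on its median, filters on the mean or on the highest group mean, no variance trend, array weights, 1 fit of all 16 arrays, 1 probe set per gene, another choice of representative probe set, all genes changed by AP20187 as sets, and leaving out each array in turn. The design text mentions Atf4 knockout siblings without tying an array to them, so no array was grouped by Atf4 genotype. No reference genome was used here, and no coordinates are given.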

Results

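Expression was measured in mouse liver under 2 ways of altering the integrated stress response (ISR), the slowing of protein synthesis and change in transcription that follow phosphorylation of the translation factor eIF2α. The mice of the first experiment, labelled TTR::Fv2E-PERK, carried Fv2E-PERK, the kinase domain of the stress kinase PERK fused to drug-binding domains and placed under a liver promoter. The compound AP20187 joins 2 such molecules and is meant to switch the kinase on without other stress. In the second experiment, with 2 arrays per group, wildtype and Alb::GC mice were fed LFD or HFD. Alb::GC mice express an active fragment of GADD34 (gene Ppp1r15a), the phosphatase subunit that removes the phosphate from eIF2α, under the albumin promoter. Signalling through eIF2α is thereby dampened in hepatocytes. Values were deposited ratios around 1 on 22626 probe sets. Changes are log2 differences with standard errors.

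The genes whose fragments the transgenes carry, and Atf4, the transcription factor translated when eIF2α is phosphorylated, were examined first. Ppp1r15a had ratios of 0.85 and 1.16 in LFD wildtype, 1.24 and 1.51 in LFD Alb::GC, 0.51 and 0.53 in HFD wildtype and 0.8 and 0.72 in HFD Alb::GC. It was thus higher in each Alb::GC array than in the wildtype arrays of the same diet. The differences of 0.44 ± 0.23 on LFD and 0.51 ± 0.23 on HFD did not pass (limma, Benjamini-Hochberg adjusted p = 0.555 and 0.49), and the one on LFD was 0.23 without LFD wildtype replicate 1. With HFD it stood at -0.87 ± 0.23 in wildtype and -0.81 ± 0.23 in Alb::GC, which did not pass (0.0529 and 0.0854), and averaged over genotypes it fell by 0.84 ± 0.16 (limma, adjusted p = 0.0156). Its interaction was 0.06 ± 0.32 (0.959). Where this probe set lies relative to the transgene fragment is not known here, so it does not check the labels. With AP20187 the endogenous ISR target Ppp1r15a rose by 1.55 ± 0.20, from a mean ratio of 0.335 ± 0.0656 to 1.06 ± 0.066 (SD, n = 4 each). Atf4 rose by 0.93 ± 0.19 with AP20187 and lay at ratios of 0.83 to 1.45 in the diet experiment. With HFD it stood at -0.17 ± 0.27 in wildtype and -0.27 ± 0.27 in Alb::GC, and between genotypes at 0.02 ± 0.27 on LFD and -0.08 ± 0.27 on HFD (limma, adjusted p = 0.69, 0.554, 0.988 and 0.951). Its other probe sets differed from this one. One lay at 1.03 to 1.18 in the 4 LFD arrays and at 0.52 to 0.67 in the 4 HFD arrays, a change of -0.86 averaged over genotypes, and had a value of 0.52 with AP20187 that did not pass (limma, adjusted p = 0.00987 and 0.0691). The other ranged from 0.16 to 1.03 in the diet experiment and from 0.18 to 0.72 in the TTR::Fv2E-PERK experiment, and passed in no comparison. Eif2ak3, the gene of PERK itself, had a value of 0.39 ± 0.15 with AP20187 that did not pass (limma, adjusted p = 0.0747), and one of 0.48 that did without AP20187 replicate 4 (0.0425). With HFD it stood at 0.02 ± 0.18 in wildtype and -0.32 ± 0.18 in Alb::GC, and between genotypes at -0.04 ± 0.18 on LFD and -0.38 ± 0.18 on HFD, none of which passed (limma, adjusted p = 0.941, 0.294, 0.956 and 0.502).

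RNA quality was read from control probe sets at both ends of the Gapdh and beta-actin transcripts. The log2 difference between the 3' and the 5' end for beta-actin lay between -0.16 and 0.21 in the 4 LFD arrays and between -0.71 and -0.33 in the 4 HFD arrays. For Gapdh it lay between 0.04 and 0.22 on LFD and between -0.31 and -0.15 on HFD. All 4 HFD arrays thus lay below all 4 LFD arrays for both transcripts, and every diet difference given here moved with this difference in the controls. On HFD the beta-actin difference also parted the genotypes, at -0.71 and -0.62 in wildtype and -0.44 and -0.33 in Alb::GC, while the Gapdh difference overlapped between them. In the TTR::Fv2E-PERK experiment the controls also moved with treatment in most arrays. For Gapdh, 3 of the 4 treated arrays lay at -0.14 to -0.10, below the untreated ones at -0.06 to -0.01, and 1 lay above them at 0.19. For beta-actin, 3 lay at 0.15, above the untreated ones at -0.18 to -0.02, and 1 lay among them at -0.04.

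**Figure D1:**
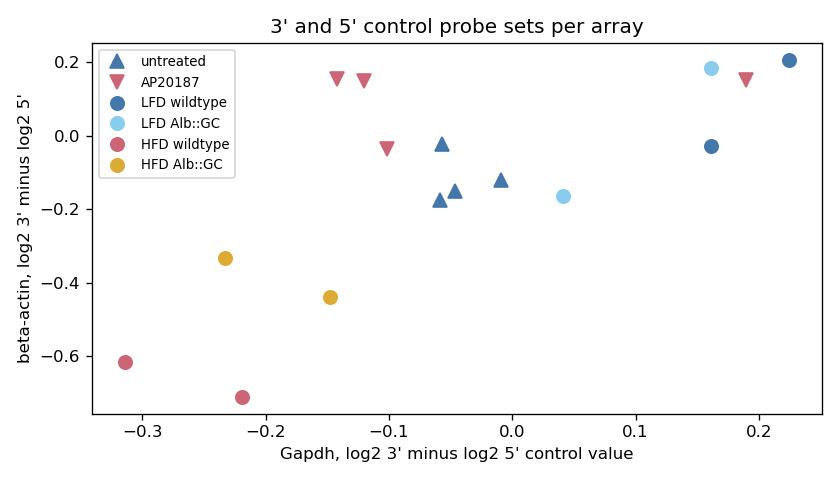
Each point is 1 array, with the log2 difference between the 3' and 5' control probe sets of Gapdh on the x axis and of beta-actin on the y axis, and marker and colour giving the group. The 4 HFD arrays lie at -0.31 to -0.15 on the x axis and -0.71 to -0.33 on the y axis, below all LFD arrays.

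The first comparison asked which liver genes respond when Fv2E-PERK is activated by AP20187. The stress genes of the ISR rose together. Fgf21, a fasting hormone secreted by the liver, went from a mean ratio of 0.108 ± 0.0419 in untreated to 3.57 ± 0.839 in treated mice (SD, n = 4 each), a log2 change of 4.54 ± 0.27 (limma, Benjamini-Hochberg adjusted p = 7.65e-05). The stress transcription factor Atf3, at the smallest ratio given in all 4 untreated arrays, rose by 4.32 ± 0.25, the mTORC1 inhibitor Ddit4 by 4.06 ± 0.17 and the stress-induced chromatin protein Nupr1 by 3.77 ± 0.30, each with no overlap between treated and untreated arrays. Of the 19 measured ISR genes, 16 rose, 1 fell and 2 did not pass, with 17 up and 1 down adjusted over the list alone. The list median was 1.54 (camera, adjusted p = 9.22e-13, and adjusted p = 0.0196 with an estimated correlation).

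**Figure D2:**
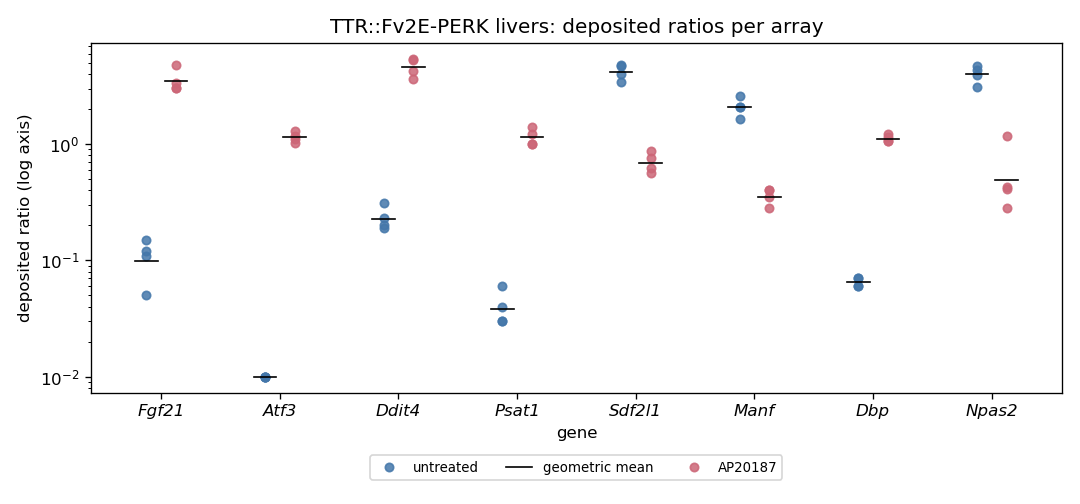
Deposited ratios on a log axis for 8 genes, named on the x axis, with each point 1 array (4 untreated, 4 AP20187) and the bar the geometric mean of a group. Fgf21, Atf3, Ddit4, Psat1 and Dbp lie higher in all treated arrays, and Sdf2l1, Manf and Npas2 lie lower.

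Genes for making and importing amino acids rose as well. Psat1, an enzyme of serine synthesis, rose by 3.75 ± 0.28, the transporter Slc7a5 by 2.85 ± 0.33, the alanine aminotransferase Gpt2 by 1.76 ± 0.18 and asparagine synthetase, Asns, by 1.69 ± 0.22. Of 17 measured genes in this list 11 rose, 1 fell and 5 did not pass, with 12 up and 1 down adjusted over the list alone. The median was 0.70 (camera, adjusted p = 4.41e-06, and adjusted p = 0.0196 with an estimated correlation). Of 12 aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, 9 rose and 3 did not pass, with 10 up adjusted over the list alone. Iars rose by 1.35 ± 0.18 and Yars by 0.93 ± 0.17 (median 0.76, camera adjusted p = 1.82e-05, and adjusted p = 0.222 with an estimated correlation). Among the transcription factors of the C/EBP family, Cebpd rose by 1.54 ± 0.20 and Cebpb by 1.30 ± 0.16. In their list of 5, which also holds Pparg, 4 rose and 1 did not pass, and 4 were up adjusted over the list alone (camera, adjusted p = 0.00157, and adjusted p = 0.222 with an estimated correlation).

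Genes of protein folding in the endoplasmic reticulum went the other way. Sdf2l1 went from a mean ratio of 4.24 ± 0.649 to 0.702 ± 0.14 (SD, n = 4 each), a change of -2.52 ± 0.17. The secreted factor Manf changed by -2.39 ± 0.17, the disulfide isomerase Pdia4 by -2.12 ± 0.20 and the chaperone partner Dnajb11 by -2.07 ± 0.19. Another Pdia4 probe set stood at 0.02 (limma, adjusted p = 0.943). Of 20 measured chaperones and degradation factors 14 fell, 1 rose and 5 did not pass, with 15 down and 2 up adjusted over the list alone (mean -1.01, camera adjusted p = 1.82e-05, and adjusted p = 0.222 with an estimated correlation). Outside the lists, Derl3, a factor of ER-associated degradation, was among the largest falls at -2.93 ± 0.25.

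Growth arrest and clock genes rose. Gadd45a showed the largest rise in this comparison at 5.57 ± 0.22, from untreated ratios of 0.02 to 0.03 to treated ratios of 3.09 to 3.73, and its size depends on the offset since the untreated values lay near the smallest value given. Gadd45g rose by 3.34 ± 0.20, the cyclin kinase inhibitor Cdkn1a by 2.93 ± 0.24 and Btg2 by 2.38 ± 0.18. Of 10 p53 targets and growth arrest genes 7 rose, 1 fell and 2 did not pass, with the same counts adjusted over the list alone (median 1.53, camera adjusted p = 4.15e-05, and adjusted p = 0.0316 with an estimated correlation). Among 14 clock genes 10 rose, 1 fell and 3 did not pass, also when adjusted over the list alone (median 1.38, camera adjusted p = 1.6e-06, and adjusted p = 0.0196 with an estimated correlation). The clock output gene Dbp rose by 3.34 ± 0.25, Per3 by 3.28 ± 0.28 and Cry1 by 1.96 ± 0.16, while the clock activator Npas2 changed by -2.88 ± 0.37. The growth regulator Myc rose by 4.30 ± 0.26, and the chemokines Cxcl2, Cxcl10 and Cxcl1 rose by 4.49 ± 0.39, 4.06 ± 0.29 and 4.06 ± 0.32.

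Lipid genes divided. Of 14 genes for making or taking up cholesterol 10 fell and 4 did not pass, with 10 down adjusted over the list alone. They were led by Idi1 at -2.37 ± 0.31 and Hmgcs1 at -2.01 ± 0.23 (median -1.29, camera adjusted p = 0.00013, and adjusted p = 0.41 with an estimated correlation). Of 11 genes of lipid droplets and lipid uptake 5 rose, 1 fell and 5 did not pass, also when adjusted over the list alone. The droplet proteins Cidec, G0s2 and Plin5 rose by 3.01 ± 0.36, 2.94 ± 0.33 and 2.41 ± 0.18, and the lipase Lpl changed by -2.25 ± 0.25. That list call had an adjusted p of 0.0361 with camera and an adjusted p = 0.311 with an estimated correlation, and quantile normalization ended it at 0.0532. It ended too without AP20187 replicate 1 (0.0547) or untreated replicate 2 (0.0506) and with the probe sets of smallest spread (0.0542). Of 16 genes for fatty acid and triglyceride synthesis 4 rose, 7 fell and 5 did not pass, with 9 down and 4 up adjusted over the list alone (camera, adjusted p = 0.266), with Thrsp at 2.39 ± 0.16 and Lpin1 at 1.46 ± 0.11 against Fasn at -2.04 ± 0.21 and Acly at -1.42 ± 0.13. Of 4 other Acly probe sets, 1 stood at 1.07 (limma, adjusted p = 0.17) and 3 at -1.57 to -1.17. Of 17 genes for fatty acid oxidation 4 rose, 7 fell and 6 did not pass, also adjusted over the list alone (camera, adjusted p = 0.615), with the pyruvate dehydrogenase kinase Pdk4 at 2.83 ± 0.51.

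Genes that mark differentiated hepatocytes mostly fell. Of 19 genes of hepatocyte identity 13 fell, 2 rose and 4 did not pass, also when adjusted over the list alone. Examples were the urea cycle enzyme Otc at -1.41 ± 0.12, Apoa1 at -0.62 ± 0.08 and the transcription factor Foxa2 at 1.10 ± 0.12 (median -0.49, camera adjusted p = 0.00893, and adjusted p = 0.498 with an estimated correlation). Of 14 complement and coagulation genes 13 fell, adjusted over the list alone as well, including C8b at -1.22 ± 0.19 and Mbl1 at -1.05 ± 0.12 (camera, adjusted p = 1.82e-05, and adjusted p = 0.325 with an estimated correlation). Of 11 genes of cytochrome P450 and conjugation 10 fell and 1 rose, also adjusted over the list alone. Gstm1 changed by -1.94 ± 0.15 and Cyp2b10 rose by 3.21 ± 0.26 (camera, adjusted p = 0.00126, and adjusted p = 0.311 with an estimated correlation). Of 9 male-biased genes 4 fell, or 5 adjusted over the list alone, with the steroid dehydrogenase Hsd3b5 at -1.67 ± 0.22 (camera, adjusted p = 0.038, adjusted p = 0.52 with an estimated correlation, and 0.0613 after quantile normalization). Of 10 NRF2 targets, genes of antioxidant defence, 6 fell and 1 rose, as they did adjusted over the list alone. Gclc changed by -1.34 ± 0.09 and Gstm3 by -1.71 ± 0.22, and the heme oxygenase Hmox1 rose by 2.90 ± 0.28 (camera, adjusted p = 0.0376, and adjusted p = 0.311 with an estimated correlation). The NRF2 call ended without AP20187 replicate 1 (0.0516) or untreated replicate 1 (0.0534) or 4 (0.0506). The male-biased call ended without AP20187 replicate 1 (0.0547), 2 (0.0694) or 4 (0.0698) or untreated replicate 2 (0.0574) or 4 (0.0714).

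Large housekeeping groups also fell. Of 72 genes of oxidative phosphorylation 67 fell and 5 did not pass, over all probe sets and adjusted over the list alone. Atp5k stood at -1.76 ± 0.11 and Ndufa4 at -1.42 ± 0.12 (median -0.77, camera adjusted p = 2.21e-19, and adjusted p = 0.222 with an estimated correlation). Of 38 proteasome genes 30 fell and 8 did not pass, again the same adjusted over the list alone. Psmd14 stood at -1.36 ± 0.17 and Psma1 at -1.17 ± 0.16 (camera, adjusted p = 2.61e-08, and adjusted p = 0.222 with an estimated correlation). Of 45 ribosomal protein genes 22 fell, 1 rose and 22 did not pass, with 24 down and 1 up adjusted over the list alone. Rps27l changed by -0.84 ± 0.16 and Rpl12 rose by 0.75 ± 0.22 (camera, adjusted p = 0.00112, and adjusted p = 0.513 with an estimated correlation). These lists kept their direction and call under quantile normalization and median centring, as did the others called here apart from the lipid droplet and male-biased lists.

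Markers of other liver cells moved too. Of 12 macrophage markers 7 fell, or 8 adjusted over the list alone, with Cd5l at -0.73 ± 0.13 and Csf1r at -0.60 ± 0.09 (median -0.49, camera adjusted p = 0.00485, and adjusted p = 0.504 with an estimated correlation). Of 10 stellate cell and fibroblast markers 7 fell, or 8 adjusted over the list alone. The largest were the collagens Col1a1 at -2.30 ± 0.42 and Col3a1 at -2.02 ± 0.16 (median -0.58, camera adjusted p = 0.00126, and adjusted p = 0.169 with an estimated correlation). Of 9 endothelial markers 4 fell, with Oit3 at -0.76 ± 0.15 and Cdh5 at -0.68 ± 0.15, but the list did not pass (camera, adjusted p = 0.154). Among exocrine pancreas markers 1 of 8 fell, Cela1 at -1.82 ± 0.14, and that list did not pass either (camera, adjusted p = 0.516). No member passed among cholangiocyte, lymphocyte, neutrophil or adipocyte markers by limma with Benjamini-Hochberg adjustment, with list adjusted p of 0.67, 0.516, 0.587 and 0.978 by camera. In 2 of those lists single members came near, Krt19 at -1.59 ± 0.59 and Elane at -0.80 ± 0.29 (limma, adjusted p = 0.0715 and 0.0638).

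The remaining lists were not called. Acute phase genes split, with 7 up, 7 down and 4 not passing, or 8 and 8 adjusted over the list alone (camera, adjusted p = 0.266). Saa3 rose by 3.81 ± 0.26, the metallothionein Mt2 by 2.46 ± 0.28 and the cytokine signalling inhibitor Socs3 by 2.27 ± 0.11. Of 15 bile acid genes 2 rose and 8 fell, or 2 and 9 adjusted over the list alone, with the export pump Abcb4 at 1.09 ± 0.16 and the uptake transporter Slc10a1 at -1.40 ± 0.13 (camera, adjusted p = 0.0526). Of 9 genes for gluconeogenesis and amino acid breakdown 2 rose and 4 fell, also adjusted over the list alone, with Igfbp1 at 1.59 ± 0.25 (camera, adjusted p = 0.913, with a median of -0.06 and a mean of 0.07). Of 6 genes for glycolysis and glucose uptake 1 rose and 2 fell, or 1 and 4 adjusted over the list alone, with the transporter Slc2a2 at -1.13 ± 0.11 (camera, adjusted p = 0.428). Of 6 female-biased genes 2 rose, also adjusted over the list alone, among them Cux2 at 2.36 ± 0.58 (camera, adjusted p = 0.428). Of 17 cell cycle genes 2 fell over all probe sets and 0 adjusted over the list alone (camera, adjusted p = 0.516). Of 10 interferon genes 2 rose, or 1 adjusted over the list alone (camera, adjusted p = 0.615), with a median of -0.19 and a mean of 0.25. The erythroid list had 2 measured genes, Alas2 at 0.41 ± 0.18 and Hba-a1 at 0.06 ± 0.48, neither of which passed (limma, adjusted p = 0.114 and 0.941).

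In all, 7724 of 22626 probe sets passed, 3107 higher and 4617 lower, of which 1180 and 1133 changed at least 2-fold (limma, Benjamini-Hochberg). The median probe set changed by -0.13, and quantile normalization, which moved that median to -0.06, gave 3449 higher and 3473 lower. Leaving out probe sets below the 40th percentile of the mean log2 ratio, an alternative added after seeing the data, ended 8 list calls. The camera adjusted p became 0.085 for amino acid genes, 0.0963 for the p53 list, 0.101 for hepatocyte identity, 0.159 for male-biased genes and 0.0514 each for clock genes, NRF2 targets and macrophage markers. For lipid droplet genes it became 0.314, with a median of -0.07. Genes that are low in 1 of the groups have low means, so this filter can take out changed genes. It removed 9 of the 12 amino acid genes past the threshold, 7 of 11 clock genes and 5 of 8 p53 genes, so the loss of those 3 calls does not measure stability. Of the 15 hepatocyte identity genes past the threshold it removed 0. Without AP20187 replicate 4, whose label is incomplete, 6801 probe sets passed.

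In wildtype mice, HFD raised genes of lipid storage and of fat synthesis and lowered genes of cholesterol synthesis. The droplet protein Cidec went from a mean ratio of 0.935 ± 0.205 on LFD to 15.3 ± 0.806 on HFD (SD, n = 2 each), a change of 3.98 ± 0.26 (limma, Benjamini-Hochberg adjusted p = 0.00326). Cidea, another droplet protein, went from 0.47 ± 0.198 to 62.4 ± 2.85 (change 6.96 ± 1.25), and the fatty acid transporter Cd36 from 0.61 ± 0.255 to 13.5 ± 0.12 (change 4.42 ± 0.40). Plin4 rose by 2.80 ± 0.44. Of 11 genes of lipid droplets and lipid uptake 7 rose and 4 did not pass, with 8 up adjusted over the list alone (median 1.91, camera adjusted p = 0.000428, and adjusted p = 0.433 with an estimated correlation). Of 16 genes of fatty acid and triglyceride synthesis 5 rose and 11 did not pass, with 10 up adjusted over the list alone. Among them were the phosphatidate phosphatase Lpin1 at 3.39 ± 0.16, the desaturase Scd1 at 2.02 ± 0.27 and Fasn at 1.36 ± 0.24 (median 0.90, camera adjusted p = 1.77e-05, and adjusted p = 0.433 with an estimated correlation). Of 14 cholesterol genes 7 fell and 7 did not pass, with 10 down adjusted over the list alone. They included Msmo1 at -2.36 ± 0.41 and Sqle at -2.29 ± 0.49 (median -1.29, camera adjusted p = 0.000428, and adjusted p = 0.648 with an estimated correlation).

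Sex-biased genes moved in opposite directions in these male mice. Of 9 male-biased genes 7 fell, also adjusted over the list alone. Among them were Hsd3b5 at -5.06 ± 0.33, the elongase Elovl3 at -3.30 ± 0.26 and Cyp7b1 at -2.55 ± 0.32 (median -1.03, camera adjusted p = 0.00121, and adjusted p = 0.604 with an estimated correlation). Both HFD values of Hsd3b5 lay at the smallest value given, so the size of its change depends on the offset. Of 6 female-biased genes 2 rose, also adjusted over the list alone, Cyp2b9 by 4.28 ± 0.35 and Cyp17a1 by 3.05 ± 0.51 (median 2.65, camera adjusted p = 0.0181, and adjusted p = 0.433 with an estimated correlation). Of 14 clock genes 7 rose and 1 fell, or 7 and 2 adjusted over the list alone. Dbp and Per2 rose by 2.37 ± 0.27 and 2.36 ± 0.43 (camera, adjusted p = 0.0107, and adjusted p = 0.433 with an estimated correlation). Of 18 acute phase genes 5 rose, or 6 with 1 down adjusted over the list alone. They included the iron-binding protein Lcn2 at 5.02 ± 0.73 and Orm2 at 3.45 ± 0.42 (camera, adjusted p = 0.0181, and adjusted p = 0.702 with an estimated correlation), and the call ended at 0.0533 without LFD wildtype replicate 2 and at 0.13 with fry. Beside these, 3 of 7 neutrophil markers rose, or 3 with 1 down adjusted over the list alone, among them S100a9 at 2.48 ± 0.36, in a list that did not pass (camera, adjusted p = 0.148).

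Of 20 ER chaperones and degradation factors 6 rose and 2 fell, or 6 and 3 adjusted over the list alone, with Sel1l at 2.34 ± 0.28 and Dnajc3 at 1.87 ± 0.20 (median 0.33, camera adjusted p = 0.017, and adjusted p = 0.691 with an estimated correlation). The 4 other Dnajc3 probe sets stood at -0.07 to 0.69, and none of them passed. The list call ended with fry (0.0869), without LFD wildtype replicate 2 (0.0785) or HFD wildtype replicate 2 (0.066) and with the probe sets of smallest spread (0.0789), which also ended that of the C/EBP list (0.0605). Of the 5 C/EBP and PPAR gamma genes 3 rose, also adjusted over the list alone, with Pparg at 2.02 ± 0.35 (camera, adjusted p = 0.017, and adjusted p = 0.433 with an estimated correlation), a call that Pparg lost under quantile normalization. Of 14 complement and coagulation genes 5 fell and 1 rose, or 8 and 1 adjusted over the list alone, with C8b at -2.34 ± 0.27 and F11 at -1.81 ± 0.25 (camera, adjusted p = 0.017, and adjusted p = 0.691 with an estimated correlation). Of 45 ribosomal protein genes 10 fell and 2 rose, or 12 and 3 adjusted over the list alone, with Rpl37a at -1.69 ± 0.29 (camera, adjusted p = 0.0445, and adjusted p = 0.702 with an estimated correlation), and that call ended under quantile normalization at 0.0637 and median centring at 0.0511. It ended likewise without LFD wildtype replicate 1 (0.183), HFD wildtype replicate 1 (0.0817) or 2 (0.0788), or HFD Alb::GC replicate 1 (0.0742) or 2 (0.0725). Of 8 exocrine pancreas markers 1 fell, also adjusted over the list alone, the elastase Cela1 from a mean ratio of 1.94 ± 0.255 to 0.2 ± 0.0424 (SD, n = 2 each), with all 8 below 0 (median -1.02, camera adjusted p = 0.0245, and adjusted p = 0.433 with an estimated correlation). The 19 ISR genes did not move as a list, with 4 up, 1 down and 14 not passing, or 5 and 4 adjusted over the list alone (camera, adjusted p = 0.542, with a median of -0.04 and a mean of 0.08). Vldlr rose by 2.65 ± 0.24 and Nupr1 by 1.86 ± 0.35, while Stc2 changed by -1.28 ± 0.28. In the erythroid list only 2 genes were measured, and Alas2 rose by 2.08 ± 0.32, a call lost under quantile normalization.

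In total 3303 of 22626 probe sets passed for wildtype, 1804 higher and 1499 lower (limma, Benjamini-Hochberg). With only 2 arrays per group this count rested on single arrays, falling to 47 without HFD wildtype replicate 2, 86 without HFD wildtype replicate 1, 1593 without LFD wildtype replicate 1, 1321 without LFD wildtype replicate 2, whose label conflicts, 2089 without HFD Alb::GC replicate 1 and 2146 without HFD Alb::GC replicate 2. Of 104 genes past the threshold that were followed under each left-out array, 6 kept their call without any 1 array of the experiment, against 5 of 73 for HFD in Alb::GC, 0 of 14 for Alb::GC on HFD and 113 of 126 for AP20187 (limma). For genes past the threshold, 71.9% of their other probe sets had the same direction, against 90% for AP20187.

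In Alb::GC mice, HFD lowered cholesterol genes and changed clock genes. Of 14 cholesterol genes 7 fell and 7 did not pass, with 13 down adjusted over the list alone. They included Mvd at -1.52 ± 0.29 and Fdps at -1.51 ± 0.28 (median -1.38, camera adjusted p = 8.17e-07, and adjusted p = 0.981 with an estimated correlation). Of 14 clock genes 6 rose and 2 fell, or 8 and 2 adjusted over the list alone. Examples were Dbp at 4.72 ± 0.27, Tef at 2.77 ± 0.13 and Npas2 at -3.42 ± 0.52 (mean 0.81, camera adjusted p = 0.0159, and adjusted p = 0.981 with an estimated correlation). Of 20 ER chaperones and degradation factors 6 rose, or 7 adjusted over the list alone, with Creld2 at 1.53 ± 0.22 and Hsp90b1 at 1.16 ± 0.17 (camera, adjusted p = 0.00447, and adjusted p = 0.981 with an estimated correlation). Of 15 bile acid genes 4 rose, or 5 adjusted over the list alone, with Cyp7a1, the rate-limiting enzyme of bile acid synthesis, at 2.16 ± 0.34 and the uptake transporter Slco1b2 at 2.21 ± 0.22 (camera, adjusted p = 0.0276, and adjusted p = 0.981 with an estimated correlation). Without LFD Alb::GC replicate 1 the calls of ER chaperones (0.0577) and bile acid genes (0.064) ended, and without HFD Alb::GC replicate 2 those of bile acid genes (0.0701) and clock genes (0.0607). The bile acid call ended at offset 64 too (0.0662). Outside the called lists, the growth arrest gene Gadd45g changed by -4.12 ± 0.29 and the stress chaperone gene Hspa1a by -3.87 ± 0.44.

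The lipid droplet list was not called in Alb::GC mice (camera, adjusted p = 0.961), with 1 of 11 genes down, Plin2 at -0.85 ± 0.17, and 0 up, also adjusted over the list alone. Cidec and Cd36, named because of their rise in wildtype, had values of 0.34 ± 0.27 and 0.74 ± 0.40 (limma, adjusted p = 0.437 and 0.273). Left-out arrays moved these to 0.65 and 0.04 for Cidec, without LFD Alb::GC replicate 1 or 2, and to 0.29 and 1.20 for Cd36, without HFD Alb::GC replicate 1 or 2, and none passed. Of 19 ISR genes 1 fell, Ddit3 at -1.23 ± 0.27, and 18 did not pass, or 1 up and 2 down adjusted over the list alone (camera, adjusted p = 0.499). In total 1531 probe sets passed, 1049 higher and 482 lower (limma, Benjamini-Hochberg), but single arrays decided the count. It fell to 18 without HFD Alb::GC replicate 2, 129 without HFD Alb::GC replicate 1, 259 and 348 without LFD Alb::GC replicates 1 and 2, and 472 and 422 without HFD wildtype replicates 1 and 2.

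The diet effects of the genotypes came from separate arrays. Across the 12393 genes their log2 changes correlated at 0.595 (Pearson) and 0.591 (Spearman), where genes are not independent replicates. Both called 421 genes higher and 134 lower (52.0 and 19.8 if independent, which they are not). Among the largest shared rises were the interferon-inducible Mndal at 4.75 ± 0.88 in wildtype and 6.49 ± 0.88 in Alb::GC, the ubiquitin protease Usp2 at 5.15 ± 0.71 and 5.37 ± 0.71, and the cell cycle kinase Wee1 at 5.13 ± 0.50 and 5.16 ± 0.50. Averaged over the genotypes, 6233 probe sets passed for diet, 3061 higher and 3172 lower (limma, Benjamini-Hochberg), but this count also moved. It was 3287 without HFD wildtype replicate 1, 3435 without HFD wildtype replicate 2, 3534 and 3610 without HFD Alb::GC replicates 1 and 2, and 3970 and 4023 without LFD Alb::GC replicates 1 and 2.

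On LFD, the comparison of Alb::GC with wildtype asked what the phosphatase fragment changes without a dietary challenge. Cell cycle genes lay lower in Alb::GC as a list, although no single gene passed. Birc5 had a value of -2.91 ± 0.53 and the replication factor Mcm2 one of -1.07 ± 0.13 (limma, adjusted p = 0.193 and 0.0992). Of the 17 cell cycle genes 0 passed over all probe sets and 4 were down adjusted over the list alone (median -0.84, camera adjusted p = 2.6e-05, and adjusted p = 0.561 with an estimated correlation). Outside the list, the mitotic ubiquitin enzyme Ube2c had a value of -4.49 ± 0.34, Lpin1 one of 1.95 ± 0.16 and the stress-responsive Ndrg1 one of 3.06 ± 0.29 (limma, adjusted p = 0.0818, 0.0818 and 0.0992).

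Other lists shifted by smaller amounts on LFD. By fry none of the 8 list calls of this comparison held, with adjusted p of 0.136 for cell cycle, P450, bile acid and stellate cell genes, 0.266 for male-biased and oxidative phosphorylation genes, 0.368 for the proteasome and 0.393 for ER chaperones. Genes of oxidative phosphorylation had a median of -0.25 (camera, adjusted p = 9.86e-07, and adjusted p = 0.735 with an estimated correlation), and genes of cytochrome P450 and conjugation one of -0.43, with Gstm1 at -0.80 ± 0.26 (camera, adjusted p = 0.000154, and adjusted p = 0.561 with an estimated correlation). Male-biased genes had a median of -0.44 (camera, adjusted p = 0.0141, and adjusted p = 0.735 with an estimated correlation). Bile acid genes had a median of -0.36, with the nuclear receptor Nr0b2 at -1.72 ± 0.32 and down adjusted over the list alone (camera, adjusted p = 0.00709, and adjusted p = 0.561 with an estimated correlation). Proteasome genes had a median of -0.21 (camera, adjusted p = 0.0333, and adjusted p = 0.794 with an estimated correlation), a call that quantile normalization ended at 0.0686. Without LFD Alb::GC replicate 1 their median was -0.06 (0.717), and without LFD wildtype replicate 1 it was -0.12 (0.387). The male-biased call ended without the same arrays, at 0.161 and 0.199. Without LFD Alb::GC replicate 1 the medians were also -0.16 for oxidative phosphorylation, -0.24 for P450, with Gstm1 at -0.45, -0.20 for bile acid genes and 0.23 for stellate cell markers, with their calls kept. Without LFD wildtype replicate 1 they were -0.26 for P450 and -0.23 for bile acid genes. Stellate cell and fibroblast markers lay higher, with a median of 0.46 and Col3a1 at 0.64 ± 0.16 (camera, adjusted p = 0.00156, and adjusted p = 0.561 with an estimated correlation), a call that ended at 0.0738 without LFD wildtype replicate 1. ER chaperones had a median of 0.26, with Creld2 at 0.65 ± 0.22 (camera, adjusted p = 0.00201, and adjusted p = 0.717 with an estimated correlation), but that median was -0.00097 without LFD Alb::GC replicate 2 (0.138) and 0.05 without LFD wildtype replicate 2 (0.157). Creld2 stood at 0.41 without LFD wildtype replicate 1. The ISR list was not called, with a median of 0.07 (camera, adjusted p = 0.277). Of 14 clock genes 2 were up and 5 down adjusted over the list alone, with Dbp at -1.98 ± 0.27, in a list that was not called (camera, adjusted p = 0.524). No probe set passed with limma and Benjamini-Hochberg adjustment, 2337 had an unadjusted p under 0.05, which was 10.3% of those tested, and no other tool was run. By limma the count was 8 at offset 64, 6 at offset 16 with the filter at the 40th percentile and 160 with all 16 arrays in 1 fit.

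On HFD, Alb::GC livers had lower values of lipid storage genes than wildtype livers. Cidec had a mean ratio of 0.905 ± 0.0212 in Alb::GC against 15.3 ± 0.806 in wildtype (SD, n = 2 each), a change of -4.01 ± 0.26 (limma, Benjamini-Hochberg adjusted p = 0.0259). Pparg, the nuclear receptor that drives fat storage, changed by -3.84 ± 0.35 (adjusted p = 0.044). Of 11 genes of lipid droplets and lipid uptake 2 fell and 9 did not pass, with 7 down adjusted over the list alone (median -2.69, camera adjusted p = 7.08e-10, and adjusted p = 0.283 with an estimated correlation). The beta-actin control moved with this and the other HFD genotype differences given here, lying higher in both Alb::GC arrays than in both wildtype arrays. The male-specific gene Hsd3b5 rose by 4.25 ± 0.33 and was the 1 male-biased gene of 9 to pass, with 6 up adjusted over the list alone (median 0.68, camera adjusted p = 1.79e-06, and adjusted p = 0.32 with an estimated correlation).

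**Figure D3:**
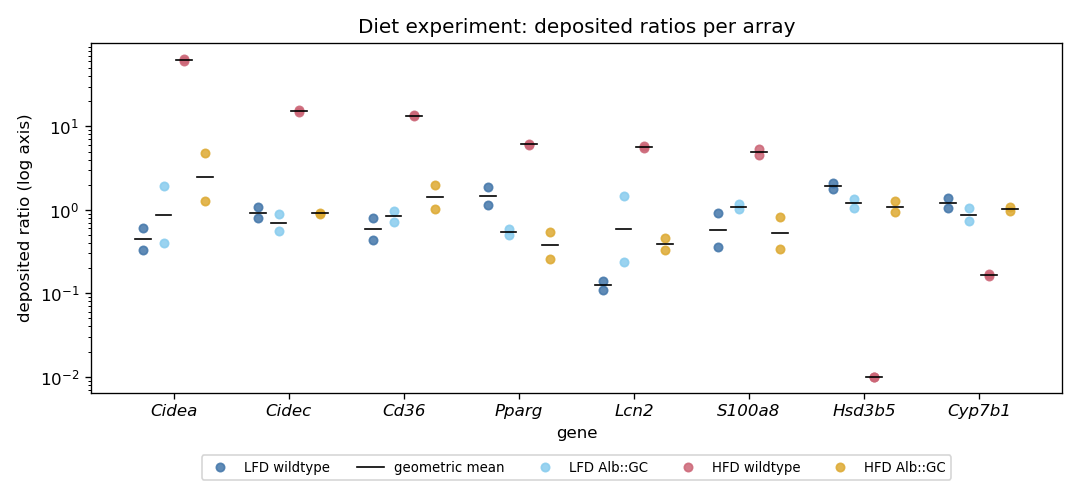
Deposited ratios on a log axis for 8 genes, named on the x axis, with each point 1 array (2 per group) and the bar the geometric mean of a group. Both HFD wildtype arrays lie above all others for Cidea, Cidec, Cd36, Pparg, Lcn2 and S100a8 and below all others for Hsd3b5 and Cyp7b1.

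Fat metabolism and inflammation lists were also lower in Alb::GC on HFD. Of 16 genes of fatty acid and triglyceride synthesis 5 were down and 1 up adjusted over the list alone, with the malic enzyme Me1 at -1.15 ± 0.14 (median -0.53, camera adjusted p = 0.00062, and adjusted p = 0.32 with an estimated correlation). Of 17 genes of fatty acid oxidation 2 were down adjusted over the list alone, with Vnn1 at -2.24 ± 0.46 (camera, adjusted p = 0.00099, and adjusted p = 0.331 with an estimated correlation). Of 18 acute phase genes 4 were down adjusted over the list alone, with Orm2 at -2.86 ± 0.42 and Lcn2 at -3.68 ± 0.73 (median -0.45, camera adjusted p = 1.79e-06, and adjusted p = 0.331 with an estimated correlation). Neutrophil markers moved with them, 5 of 7 down adjusted over the list alone, with S100a8 at -3.10 ± 0.50 and S100a9 at -2.50 ± 0.36 (median -0.76, camera adjusted p = 3.62e-06, and adjusted p = 0.32 with an estimated correlation). Of 10 NRF2 targets 4 were down adjusted over the list alone, with Gclc at -1.24 ± 0.14 (median -0.57, camera adjusted p = 3.62e-06, and adjusted p = 0.211 with an estimated correlation). Lymphocyte markers had a median of -0.58, with Cd79b at -1.24 ± 0.33 and 2 of 8 down adjusted over the list alone (camera, adjusted p = 0.0253, and adjusted p = 0.331 with an estimated correlation). The p53 list had a median of -0.51 with 0 of 10 past either way (camera, adjusted p = 0.0253, and adjusted p = 0.32 with an estimated correlation). Without HFD wildtype replicate 2 the lymphocyte median was -0.15 (0.205), against -1.26 without HFD wildtype replicate 1, where its call was kept, and the p53 call ended (0.0509). The lymphocyte call ended also without HFD Alb::GC replicate 2 (0.0679), and the p53 call without HFD wildtype replicate 1 (0.0817). With the probe sets of smallest spread both ended (0.0592 and 0.0566), and the lymphocyte call ended with all 16 arrays in 1 fit (0.0564). Cd79b stood at -0.76 without HFD Alb::GC replicate 2. With limma's fry the calls of fatty acid oxidation (0.146), acute phase genes (0.0986) and lymphocyte markers (0.183) ended. None of the genes named in these lists passed over all probe sets.

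ER chaperones lay higher in Alb::GC on HFD, with 3 of 20 up adjusted over the list alone and Creld2 at 1.23 ± 0.22 (median 0.39, camera adjusted p = 1.14e-05, and adjusted p = 0.331 with an estimated correlation). Bile acid genes did as well, with 5 of 15 up adjusted over the list alone, Cyp7b1 at 2.31 ± 0.32 and Slco1a1 at 1.72 ± 0.21 (camera, adjusted p = 0.00287, and adjusted p = 0.331 with an estimated correlation). Female-biased genes had a median of -1.59, with Cyp2b9 at -2.35 ± 0.35 and 1 of 6 down adjusted over the list alone (camera, adjusted p = 0.0418, and adjusted p = 0.32 with an estimated correlation). That call ended without HFD wildtype replicate 2 (0.0809) or HFD Alb::GC replicate 2 (0.128) and with the probe sets of smallest spread (0.0554). The ISR list had a median of -0.18, with Nupr1 at -1.82 ± 0.35, Vldlr at -1.72 ± 0.24 and 2 of 19 down adjusted over the list alone (camera, adjusted p = 0.0495, and adjusted p = 0.331 with an estimated correlation). By fry the ER chaperone (0.0871) and ISR (0.183) calls ended, and without HFD Alb::GC replicate 2 the bile acid median was 0.15, from 0.27. The ISR call ended without HFD wildtype replicate 2 (0.179), HFD Alb::GC replicate 1 (0.0763) or 2 (0.0679), or LFD wildtype replicate 1 (0.0619) or 2 (0.059). It ended as well with no variance trend (0.0516), the filter on the highest group mean (0.0504) and the probe sets of smallest spread (0.0601). The ISR median was -0.32 without HFD wildtype replicate 1, with its call kept, and -0.10 without HFD Alb::GC replicate 2. Of the pancreas list, which was not called (camera, adjusted p = 0.051), the elastase Cela1 rose by 2.37 ± 0.19. Outside the lists, the growth factor receptor Egfr rose by 2.54 ± 0.26, although its 4 other probe sets ran from -0.22 to 2.83 and none of them passed, while the lectin Lgals1, the endothelial Esm1 and the matrix protein Ccdc80 changed by -3.66 ± 0.32, -3.94 ± 0.41 and -3.09 ± 0.27. In total 30 of 22626 probe sets passed, 8 higher and 22 lower, and 2525 had an unadjusted p under 0.05 (limma, Benjamini-Hochberg). Leaving out any 1 of the 8 arrays of the experiment left 0 past the threshold, as did quantile normalization, by limma, and no other tool was run. The count was 123 at offset 1, 151 at offset 64, 160 at offset 16 with the filter at the 40th percentile, 210 with array weights, 256 with all 16 arrays in 1 fit, 15 with no variance trend and 19 with 1 probe set per gene.

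The difference between the diet effects of the genotypes was tested itself. For lipid droplet genes the diet effect was lower in Alb::GC by a median of -2.05, with 6 of 11 down adjusted over the list alone (camera, adjusted p = 4.28e-07, and adjusted p = 0.267 with an estimated correlation). Cidec had an interaction of -3.63 ± 0.37 and Cd36 one of -3.67 ± 0.56 (limma, adjusted p = 0.089 and 0.139). Male-biased genes had a median of 1.18, with 8 of 9 up adjusted over the list alone and Hsd3b5 at 4.94 ± 0.47 (camera, adjusted p = 2.79e-07, and adjusted p = 0.28 with an estimated correlation). Female-biased genes had one of -2.89, with 1 of 6 down adjusted over the list alone (camera, adjusted p = 0.00804, and adjusted p = 0.267 with an estimated correlation). Bile acid genes had one of 0.85, with 7 of 15 up adjusted over the list alone and Cyp7b1 at 2.75 ± 0.45 (camera, adjusted p = 1.68e-05, and adjusted p = 0.267 with an estimated correlation), and one of 0.56 without LFD wildtype replicate 1.

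Genes of fatty acid synthesis had an interaction median of -0.62, with Scd1 at -2.39 ± 0.38 and 6 of 16 down adjusted over the list alone (camera, adjusted p = 7.53e-06, and adjusted p = 0.267 with an estimated correlation). Acute phase genes had one of -0.50, with Lcn2 at -5.62 ± 1.04 and 7 of 18 down adjusted over the list alone (camera, adjusted p = 1.68e-05, and adjusted p = 0.47 with an estimated correlation), and one of -0.23 without LFD Alb::GC replicate 2. Neutrophil markers had one of -1.03, with 4 of 7 down adjusted over the list alone (camera, adjusted p = 0.000161, and adjusted p = 0.28 with an estimated correlation). NRF2 targets and ISR genes had medians of -0.29 and -0.25, with 1 of 10 and 3 of 19 down adjusted over the list alone (camera, adjusted p = 0.00894 and 0.0188, and adjusted p = 0.267 and 0.34 with an estimated correlation). The ISR median was -0.0069 without LFD Alb::GC replicate 2 (0.137), and the call ended also without LFD wildtype replicate 1 (0.0788) or HFD wildtype replicate 2 (0.068). P450 and conjugation, complement and proteasome genes had medians of 0.36, 0.33 and 0.27, with 2, 2 and 0 up adjusted over the list alone (camera, adjusted p = 0.0161, 0.0307 and 0.0422, and adjusted p = 0.553, 0.651 and 0.728 with an estimated correlation). By fry the calls of acute phase genes and complement (0.158 each), neutrophil markers (0.0637), ISR genes (0.212), P450 (0.113) and the proteasome (0.325) ended. The proteasome call ended after quantile normalization (0.0589) or median centring (0.055) and with no variance trend (0.0519), and the complement call at offset 64 (0.0536). Without LFD Alb::GC replicate 1 the P450, complement and proteasome calls ended (0.0525, 0.195 and 0.43), as they did without LFD wildtype replicate 1 (0.0788, 0.162 and 0.24). Without HFD Alb::GC replicate 1 those of P450 (0.0852) and the proteasome (0.0905) ended, and without HFD Alb::GC replicate 2 or HFD wildtype replicate 1 those of complement (0.0995 and 0.0702) and the proteasome (0.0544 and 0.0702). The latter ended without HFD wildtype replicate 2 as well (0.0937). Among single genes, Ccdc80 at -5.50 ± 0.39, Tceal8 at -2.11 ± 0.19 and Vegfb at -1.89 ± 0.18 had the smallest p-values below 0 (limma, adjusted p = 0.087, 0.0887 and 0.0887). No probe set passed for the interaction with limma and Benjamini-Hochberg adjustment, 2517 had an unadjusted p under 0.05, and none passed for Alb::GC against wildtype averaged over diets, where 2596 did. At offsets 1 and 64, and 16 with the filter at the 40th percentile, these counts were 12, 49 and 26 for the interaction and 12, 11 and 11 for genotype averaged. With all 16 arrays in 1 fit they were 212 and 162. The interaction also had 5 with no variance trend and 2 and 3 with the filters at the 60th and 40th percentile, and genotype averaged had 9 at the 60th.

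**Figure D4:**
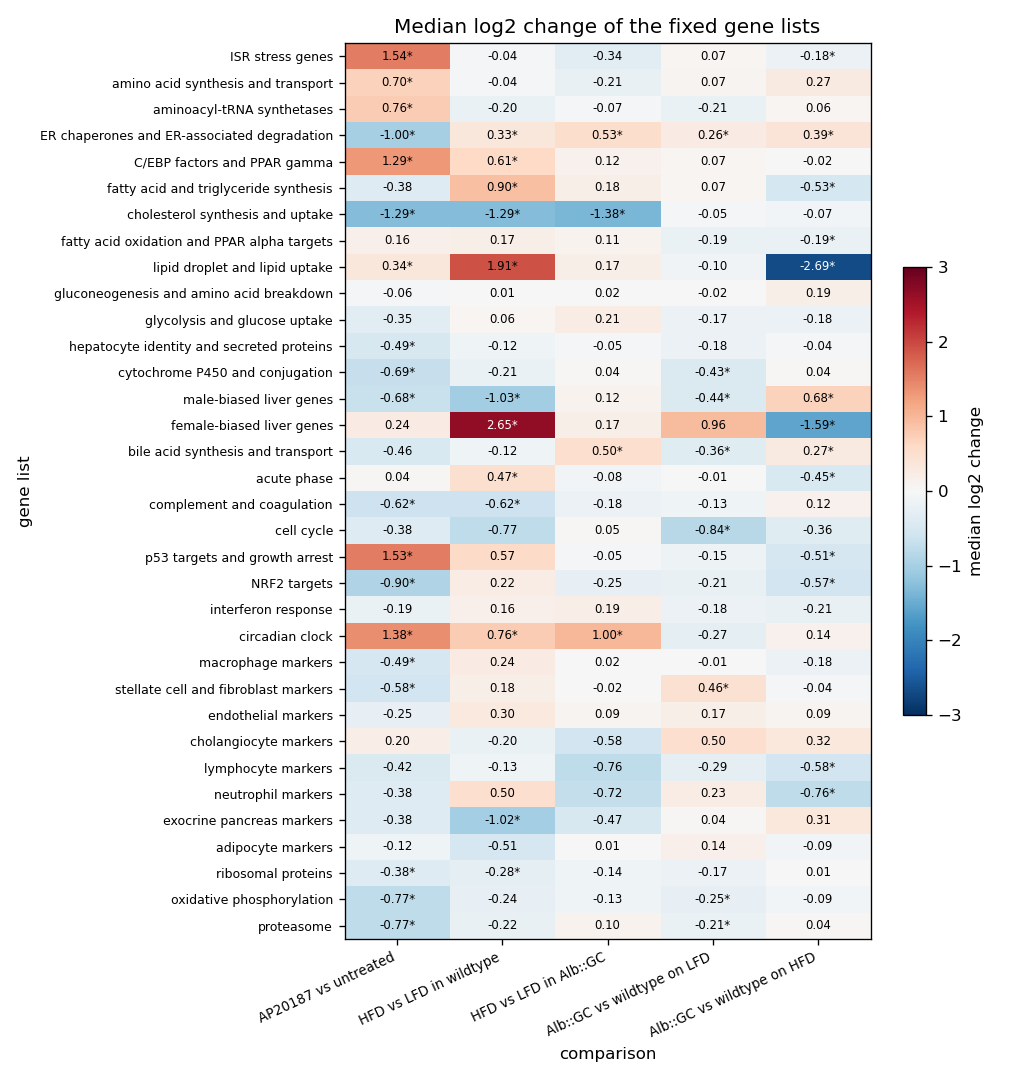
Median log2 change of 34 gene lists, 1 per line of the y axis, in the 5 comparisons on the x axis, with colour and printed value giving the median and a star marking lists with a camera adjusted p under 0.05 at the preset correlation. The ISR list stands at 1.54 with AP20187 and is starred in 1 other comparison, Alb::GC against wildtype on HFD, at -0.18.

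The genes changed by AP20187 were then followed in the diet experiment, which shares no array with the first. The 200 genes raised most by AP20187 were higher on HFD in wildtype, with a median of 0.36 and 41 of 200 past the threshold upward against 6 downward (camera, adjusted p = 6.54e-05, and adjusted p = 0.518 with an estimated correlation). On HFD in Alb::GC their median was 0.17, with 25 up and 8 down (camera, adjusted p = 0.0409). On HFD they lay lower in Alb::GC than in wildtype, with a median of -0.14 (camera, adjusted p = 0.0406), and the interaction had a median of -0.09 (camera, adjusted p = 0.00683). On LFD the median was 0.07 (camera, adjusted p = 0.0409). Each of these calls had an adjusted p = 0.518 with an estimated correlation. Without any 1 array the call on HFD in wildtype held, and the others ended without single arrays. The highest adjusted p was 0.0923 on HFD in Alb::GC (without LFD Alb::GC replicate 1), 0.146 between genotypes on HFD (without untreated replicate 1), 0.0828 for the interaction and 0.45 on LFD (both without LFD wildtype replicate 2). Taking all genes raised by AP20187 in place of 200 turned the medians of the last 3 comparisons to 0.08, 0.11 and -0.04.

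The 200 genes lowered most by AP20187 had a median of -0.34 on HFD in wildtype, with 31 down and 8 up, and one of -0.21 in Alb::GC, with 17 down and 5 up (camera, adjusted p = 0.0406 for both, and adjusted p = 0.518 with an estimated correlation). Single arrays ended these calls too, at up to 0.129 in wildtype (without AP20187 replicate 2) and 0.144 in Alb::GC (without untreated replicate 4). They were not called for Alb::GC against wildtype on LFD, on HFD or for the interaction (camera, adjusted p = 0.87, 0.748 and 0.854). Across the 12393 genes the changes with AP20187 correlated with those of HFD at 0.121 in wildtype and 0.108 in Alb::GC (Pearson, with Spearman 0.101 and 0.105), and with those of genotype at 0.0529 on LFD and 0.0097 on HFD. Of the genes raised by AP20187, 226 were also higher on HFD in wildtype, where independent lists would share 131.4, and 272 were lower in both, where they would share 183.2. For HFD in Alb::GC, 161 were higher in both against 87.1, and 68 lower in both against 61.4.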

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

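The comparisons with sample splits were planned, and the 3 tests of the lipid droplet pattern, on adipocyte markers, scaling and RNA quality, were chosen after the result was seen.

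In the TTR::Fv2E-PERK experiment, 87 measures were examined in each group of 4 arrays for an array set apart from the other 3, by the gap to its nearest neighbour as a share of the group's range. Chance sets about 1 in 20 apart, and 1 measure stood out in the untreated group and 7 in the treated group. In the untreated group this was Gadd45a in replicate 2, with a share of 1, where the ratios were 0.03 against 0.02 and so differ by 1 step of rounding. In the treated group the share was 0.917 for Derl3 in replicate 4, 0.931 for C8b, 0.954 for Fasn and 0.896 for Hsd3b5 in replicate 3, and 0.894 for Otc in replicate 1. The 3' to 5' control of Gapdh stood apart in replicate 3, at 0.878, and that of beta-actin in replicate 1, at 0.98.

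Several lists differed in their diet effect between the genotypes by a test of the interaction itself (limma's camera, adjusted over the lists, with no single probe set past the threshold by limma, where 2517 had an unadjusted p under 0.05). The diet effect was lower in Alb::GC for lipid droplet genes (adjusted p = 4.28e-07), fatty acid synthesis (7.53e-06), acute phase genes (1.68e-05), neutrophil markers (0.000161), female-biased genes (0.00804), NRF2 targets (0.00894) and ISR genes (0.0188). It was higher in Alb::GC for male-biased genes (adjusted p = 2.79e-07), bile acid genes (1.68e-05), P450 and conjugation (0.0161), complement (0.0307) and the proteasome (0.0422). The genes raised by AP20187 had a lower diet effect in Alb::GC as well (adjusted p = 0.00683). None of these calls held with an estimated correlation. By fry those of acute phase, neutrophil, ISR, P450, complement and proteasome genes and of the genes raised by AP20187 ended. Without LFD Alb::GC replicate 2 the ISR call ended (0.137), and without LFD Alb::GC replicate 1 those of P450 (0.0525), complement (0.195) and the proteasome (0.43), each among other arrays that did so. That of the genes raised by AP20187 ended without LFD wildtype replicate 2, and its direction reversed when all genes raised by AP20187 were taken.

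Lipid droplet genes lay lower in Alb::GC than in wildtype on HFD, with a list median of -2.69. Fat tissue carried over into the HFD wildtype samples would bring adipocyte transcripts with it, but the mean change of the 3 measured adipocyte markers was 0.0671 ± 0.396, where carry-over predicted a fall of at least 1 log2 unit (Adipoq -0.25, Retn -0.09, Lep 0.54). Scaling between arrays is argued against by quantile normalization, which left the list median at -2.21 and its call in place, and the changes of Cidec and Pparg at -3.11 and -3.22, from -4.01 and -3.84, although their single calls ended at adjusted p of 0.126 and 0.136 (limma). RNA quality and genotype cannot be told apart here, since both HFD Alb::GC arrays lay above both HFD wildtype arrays in the beta-actin 3' to 5' difference, by a gap of 0.179, and other probe sets, 5 of 6 with the direction of their gene, exist for only 3 of the 11 list members. An effect of the Alb::GC transgene remains a candidate explanation beside it and was not tested apart from it.

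The planned count of sample splits for genotype averaged over diets decides nothing, because the real split gave 0 probe sets, which all 35 of 35 splits reach. The split by diet gave 5428, a structure of the samples that a fit of 2 groups leaves in the spread.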

How the results depend on the processing

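No paired analysis was possible, since the labels only number the arrays. Filters at the 40th percentile, the planned offset of 16 with that filter, offsets of 0.01 and 0.2, the filter on the highest group mean and the choice of probe set by smallest spread were added after seeing the data. The cause was not tested, except that filters and 1 probe set per gene test fewer probe sets, and that larger offsets shrink every log2 change. Over alternatives and left-out arrays, 118 of 176 counts stayed within 1.5 times and 148 of 150 correlations within a standard error from left-out arrays. Direction and threshold side held in 230 of 330 tests of AP20187 sets, 1403 of 1616 of lists and 6759 of 8001 of named genes. With an estimated correlation 4 list calls held, all for AP20187, and 64 ended. What dim probe sets limit is unknown.

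Counts past the threshold moved as follows. The filter at the 60th percentile gave 4284 for AP20187, 1928 for HFD in wildtype, 3111 for HFD averaged over genotypes, 9 for genotype averaged over diets and 2 for the interaction. With 1 probe set per gene they were 4264 for AP20187, 1860 for HFD in wildtype, 3546 for HFD averaged and 19 for Alb::GC on HFD. The filter at the 40th percentile gave 4010 for HFD averaged and 3 for the interaction. A fit of all 16 arrays gave 5110 for HFD in wildtype, 3519 for HFD in Alb::GC, 160 for Alb::GC on LFD, 256 for Alb::GC on HFD, 162 for genotype averaged and 212 for the interaction. For Alb::GC on HFD the count was 123 at offset 1, 151 at offset 64, 160 at offset 16 with the filter, 0 after quantile normalization, 15 with no variance trend and 210 with array weights. For the interaction it was 12, 49 and 26 at those offsets and 5 with no variance trend. For genotype averaged it was 12, 11 and 11, and for Alb::GC on LFD 8 at offset 64 and 6 at offset 16 with the filter. Leaving out 1 array gave 47 to 2590 for HFD in wildtype, 18 to 1680 in Alb::GC, 3287 to 5035 averaged, 6162 to 7548 for AP20187, and 0 to 0 for Alb::GC on LFD, Alb::GC on HFD, genotype averaged and the interaction. A lone array is assumed to vary like the other groups.

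For the genes lowered by AP20187, the median on HFD in wildtype lost its call at offset 1 (-0.1685), offset 64 (-0.004311), the filters at the 60th (-0.1834) and 40th percentile (-0.2163), offset 16 with the filter (-0.01618), array weights (-0.3279), 16 arrays (-0.3162), all called genes (-0.1637) and an estimated correlation (-0.3358). On HFD in Alb::GC it did so at offset 1 (-0.0279), 64 (-0.0008869) and 0.2 (-0.128), with median centring (-0.1384), no variance trend (-0.1632), array weights (-0.1653), all called genes (-0.04008), the filter at the 40th percentile (-0.01444), offset 16 with the filter (-0.001266), and an estimated correlation or fry (-0.2055), and it reversed at the 60th percentile (0.04376). All called genes gained a call for Alb::GC on LFD (-0.1401). Leaving out 1 array gave -0.4129 to -0.2431 in wildtype and -0.242 to -0.1239 in Alb::GC.

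For the genes raised by AP20187, an estimated correlation ended the call on HFD in wildtype (0.3639) and in Alb::GC (0.1707), where median centring (0.1777) and offset 0.01 (0.1756) did too, with 0.1313 to 0.2562 when 1 array was left out. For Alb::GC on HFD the call ended at offset 64 (-0.0009892), 0.01 (-0.1128) and 0.2 (-0.1083), with quantile normalization (-0.06514), median centring (-0.152), array weights (-0.1123), 16 arrays (-0.1239), the filter at the 40th percentile (-0.02805), offset 16 with the filter (-0.004122), and an estimated correlation or fry (-0.1376), and it reversed at the 60th percentile (0.01309) and with all called genes (0.08229). Leaving out 1 array gave -0.176 to -0.08146. For Alb::GC on LFD it ended at offset 64 (0.0001125) and 0.2 (0.02753), with quantile normalization (0.1015), median centring (0.121), array weights (0.01165), the filter at the 40th percentile (0.04532), smallest spread (0.0318), and no variance trend, an estimated correlation or fry (0.07244). It reversed at offset 1 (-0.002903), the 60th percentile (-0.02029), all called genes (-0.04181) and offset 16 with the filter (-0.0006492), and lay at -0.06144 to 0.1077 when 1 array was left out. For the interaction it ended at offset 64 (-0.0002787) and with an estimated correlation or fry (-0.09357), and reversed at the 60th (0.05818) and 40th percentile (0.01255), with all called genes (0.1097) and offset 16 with the filter (0.0004257), with -0.2234 to -0.06593 when 1 array was left out. The correlations with AP20187 at the 60th percentile were 0.1705 for HFD in Alb::GC and 0.1643 in wildtype.

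List medians reversed for ER chaperones in Alb::GC on LFD without LFD Alb::GC replicate 2 (-0.0009678, up to 0.3169 without replicate 1), and for lipid droplet genes with AP20187 at the 40th percentile (-0.06723). In the diet experiment that filter ended, by camera, the calls on HFD in wildtype of ER chaperones (0.0613), acute phase (0.24), cholesterol (0.0753), complement (0.0613), male-biased (0.0508) and ribosomal genes (0.421). It ended those between genotypes on HFD of bile acid (0.244) and p53 genes (0.092), on LFD of the proteasome (0.0737), and for the interaction of NRF2 targets (0.0557), complement (0.21) and the proteasome (0.0557). Since changed genes can have low means, it removed, of those past the threshold on HFD in wildtype, 6 of 7 cholesterol, 9 of 12 ribosomal, 3 of 6 complement, 3 of 7 male-biased and 2 of 5 acute phase genes and 1 of 8 ER chaperones. Only the lost cholesterol and ribosomal calls do not measure stability. The planned filter at the 60th percentile ended 22 list calls by camera. With AP20187 these were amino acid (0.0897), hepatocyte (0.105), lipid droplet (0.119), macrophage (0.119), male-biased (0.229), p53 (0.129) and ribosomal genes (0.282). On HFD in wildtype they were the C/EBP list, acute phase and male-biased genes (0.0623 each), ER chaperones (0.0639), ribosomal genes (0.847) and complement (0.739, with a median of -0.02996), and in Alb::GC ER chaperones (0.0807). Between genotypes on HFD they were bile acid (0.344), fatty acid oxidation (0.101), male-biased (0.0952) and p53 genes (0.34), on LFD male-biased genes (0.0645) and the proteasome (0.177), and for the interaction complement (0.809) and the proteasome (0.198). Offset 16 with the filter ended those of hepatocyte (0.0921) and male-biased genes (0.144) with AP20187, of ER chaperones (0.093), acute phase (0.089), complement (0.209) and ribosomal genes (0.407) on HFD in wildtype and of clock genes in Alb::GC (0.0598), of bile acid genes between genotypes on HFD (0.218), and of NRF2 targets (0.0763) and complement (0.472) for the interaction. With the probe set of smallest spread, genes reversed on HFD in wildtype for Ap2a2 (-0.222), Cebpg (-0.2256), Cox5a (-0.7437), Mt1 (-0.07264), Rpl41 (-0.6131), Rps9 (-0.638) and Sox9 (-0.9806). In Alb::GC on HFD they did so for Cox5a (-0.493), Jade1 (-0.03032), Psmc6 (-0.1957), Rps9 (-0.5572) and Sox9 (-0.5082), with AP20187 for Pck1 (0.06651), and for Tbx15 between genotypes on HFD (-0.0315).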

Other observations

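The tests on clock genes, on probe sets of one gene and on control transcripts were chosen after the results were seen, and the 2 counts of sample splits were planned.

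Outside the fixed lists, HFD changed several genes by large amounts in both genotypes. The mitochondrial carrier Slc25a51 rose by 5.10 ± 0.50 in wildtype and 4.55 ± 0.50 in Alb::GC. The nicotinamide methyltransferase Nnmt rose by 4.21 ± 0.31 and 4.18 ± 0.31, and the uridine phosphorylase Upp2 by 2.41 ± 0.53 and 4.24 ± 0.53. The stress chaperone gene Hspa1a changed by -3.99 ± 0.44 in wildtype and -3.87 ± 0.44 in Alb::GC. The erythroid genes moved apart, with Alas2 at 2.17 ± 0.23 and Hba-a1 at -1.97 ± 0.31 in the diet effect averaged over genotypes (limma, adjusted p = 0.00337 and 0.00893).

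Clock genes changed with AP20187 and HFD. If time of day or feeding at harvest differed between groups, clock activators and the genes they drive, which peak at opposite times, would move apart. With AP20187 the mean change of 8 driven genes minus that of 3 activators was 2.82 ± 0.15. The activator mean of -0.95 rests on Npas2, the only 1 past the threshold. With HFD averaged over genotypes the difference was 3.53 ± 0.18, and 2 activators fell. Harvest time, feeding, or PERK signalling or the diet acting on the clock could give both. With no harvest time in the labels, these stay open.

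HFD changed many probe sets, 6233 when averaged over genotypes, and its arrays also differed in the control transcripts. If RNA quality or labelling acted on single probe sets, other probe sets of a called gene would share its direction in under 60% of cases, and if not in over 75%, and the share was 69.5%, between the bounds. The lowest LFD array and the highest HFD array were 0.168 log2 units apart in the beta-actin 3' to 5' difference, with no overlap, so a processing batch and the diet cannot be told apart without array dates. In a fit of 2 groups, the real split of 8 arrays gave 5428 probe sets for diet and 7724 for AP20187. No other of 35 splits each gave more than 1. The others mix the groups, which widens their spread, so chance is not excluded.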
